A study of Arabidopsis thaliana with 30 samples.

How the data were processed

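Gene expression was measured on 1-colour Affymetrix arrays in whole seedlings of the Columbia wild type and of pifq, in 10 groups of 3 arrays. Per the labels' protocols, seeds were kept at 4 °C in the dark for 5 days and seedlings were grown at 21 °C without sucrose, and biological replicates were grown, extracted and processed separately. The deposited values are log2 expression values computed by the authors with RMA (background correction, quantile normalization and a summary over the probes of a probe set), per the submitters' processing notes, which give no version. They ranged from 2.42 to 14.16, with array medians of 5.55 to 5.64. Quantile normalization gives the arrays nearly equal distributions, so a change of total RNA or a shift of most transcripts one way could not be seen, and RMA compresses folds of dim and very bright probe sets. No scanner files, scan dates or array batches were used here, and the number of arrays, 3 per group, limits the precision.

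The table held 22810 probe sets on 30 arrays, each matched to its sample by name. After 64 control probe sets were left out, 22746 were tested with no filter on level. Genes were named from the platform annotation joined to the RefSeq gene table by gene ID. Of the tested probe sets 13436 (59.1%) had exactly 1 locus, 503 had several genes, 77 had a gene ID without a locus in that table and 8730 had no gene in the annotation used here, and only probe sets with 1 locus were named. Of these, 1550 had a symbol other than the locus ID. Many well-known genes therefore have no name here, and the absence of a gene from the text says nothing about its expression.

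A linear model with 1 mean per group was fitted to all 30 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that all groups share an estimate of the spread (20 residual and 9.44 prior degrees of freedom). It gave 18 comparisons: far-red against white light in each genotype at 1, 3 and 24 h, the difference of these responses between genotypes (the interaction), pifq against the wild type in each of the 5 conditions, WL24 against WL0 in each genotype, FR3 against FR1 in the wild type, and the 24 h against the 3 h response in the wild type. WL24 was the control of FR24, and WL0 that of FR1 and FR3. P-values are two-sided and adjusted by the Benjamini-Hochberg method over the 22746 probe sets of a comparison, and a probe set was called at an adjusted p under 0.05, with calls of at least 2-fold counted beside.

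The groups, the rule for naming genes, the fixed lists and the tests and alternatives were fixed before the data were examined, apart from the added families and the alternative and tests that the closing text names as chosen later. The rule named, for the wild-type far-red comparisons, the 10 largest rises and 5 largest falls among called probe sets with a gene symbol whose 3 arrays in 1 group lay beyond the 3 of the other, and 6 rises and 4 falls elsewhere, without the condition on array order for differences of responses. It also named every shade-response marker with a probe set of its own in the annotation, and of each other list up to 6 called members, or 2 if none was called. The probe set of highest mean stood for a gene; 1 named locus had a second probe set, and 0 called disagreements in direction were found.

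Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and repeated with an estimated correlation. Of 20 fixed lists, 10 had the 3 or more probe sets needed. Only list members with a probe set named here are counted. These were 3 of 20 shade-response markers, 6 of 39 auxin genes and 8 of 20 wall-loosening genes. They were 7 of 36 photosystem, 5 of 26 chlorophyll and carotenoid and 3 of 12 flavonoid genes. The other members may have been tested without a name, so a list result does not stand for the whole pathway. The lists for the PIF genes, brassinosteroid, cell division, seed storage and late embryo genes and heat shock had 0 probe sets of their own, so no result is given for them. A further 30 gene families were chosen by symbol after the table was seen and before any result was computed, and 26 with at least 5 probe sets were tested. A symbol can be shared by unrelated genes, and 3 of the 26 that hold such genes are counted here but not reported further. With an estimated correlation 31 of 52 list calls held in the fixed lists and 7 of 45 in the added families. A called list whose camera p stands alone in the text held with an estimated correlation.

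The share of the wild-type response seen in pifq, the correlation of responses with genotype differences and the overlap of calls were computed as stated beside them. Each was set against simulated unchanged groups where control arrays were shared. The fit was tested on simulated data with the real means and spreads, in which 200 of 22746 probe sets were given a change for it to recover. It recovered 94% of 1.5-fold and 100% of 2-fold changes for WT FR1 against WL0, 91% and 100% for WT FR3 against WL0, 88.1% and 100% for WT FR24 against WL24, 65.7% and 97% for the interaction at 3 h, and 91% and 100% for pifq against WT at WL0. Of the probe sets called there, 10 of 214, 7 of 207, 13 of 211, 11 of 193 and 18 of 219 were unchanged ones. A small set of other probe sets, shifted together for a list test, was not counted among the unchanged. The simulated noise was independent between probe sets and equal between arrays. Fewer probe sets were changed than were called in these comparisons of the data, so the rates need not hold for the data.

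The alternatives were a replicate block, leaving out the dimmest 30% of probe sets, quantile normalization, centring of arrays on their medians, eBayes with trend and robust settings, array weights, fitting only the arrays compared, only probe sets with 1 locus, WL0 as the control of FR24, and leaving out each array in turn. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.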

Results

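Shade avoidance is the change in growth and gene expression that plants make when their light becomes rich in far-red, as it does under leaves. It was examined in whole Arabidopsis seedlings of the Columbia wild type and of pifq, a line mutated in PIF1, PIF3, PIF4 and PIF5, whose products are transcription factors that act downstream of the phytochrome light receptors. Seedlings grew for 2 days in white light of 19 µmol/m2/s at a red to far-red ratio of 6.48 (WL0). They then either stayed in that white light for another 24 h (WL24) or had far-red light added, at a ratio of 0.006, for 1 h (FR1), 3 h (FR3) or 24 h (FR24). Each of the 10 groups held 3 biological replicates, grown separately per the labels, with 1 array per replicate and 30 arrays in all, a number that limits the precision of every value. Levels are log2 RMA signals given as mean ± SD (n = 3 arrays), and changes are log2 differences ± SE from the limma fit unless a fold is named.

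The genes mutated in pifq could not be read first as a check of the genotype labels, because none of the 4 PIF genes had a probe set of its own in the annotation used here. Arrays of 1 group correlated at 0.9945 to 0.9983 across probe sets, and arrays of different groups at 0.9577 or more. No array repeated another's values. The first principal component, with 55% of the variance, placed WL0 lowest and the 24 h arrays highest in both genotypes.

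**Figure D1:**
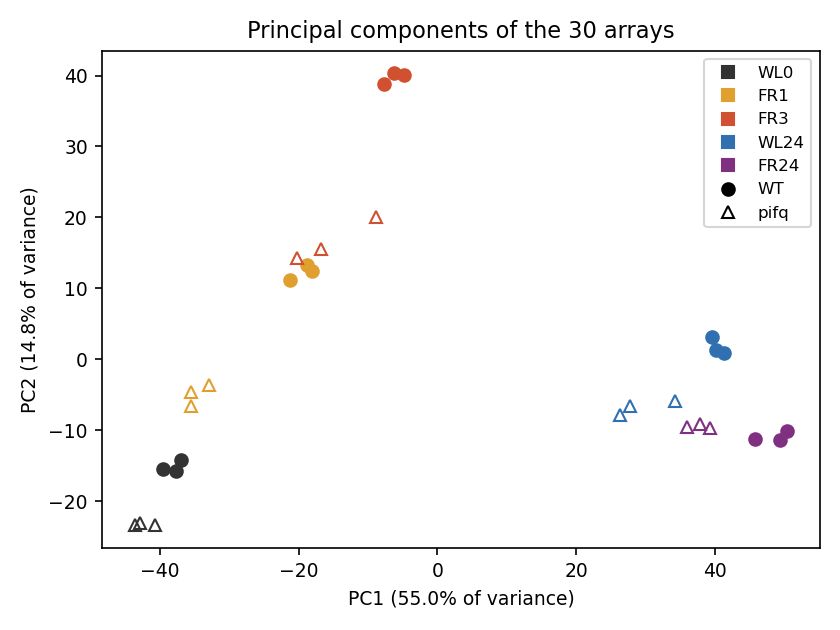
Each of the 30 arrays is 1 point on principal component 1 (x axis, 55% of the variance) and component 2 (y axis, 14.8%), with filled circles for the wild type, open triangles for pifq and 1 colour per light condition. Wild-type FR3 arrays lay at 38.79 to 40.31 on component 2, above all 3 pifq FR3 arrays, the lowest of which lay at 14.31.

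After 1 h of far-red light, IAA29 (AT4G32280), which encodes an Aux/IAA repressor of auxin response, rose 25.7-fold in the wild type, from 4.63 ± 0.09 to 9.32 ± 0.14. HAT2 (AT5G47370), a homeodomain-leucine zipper gene, rose by 1.90 ± 0.09, and GH3.3 (AT2G23170), whose product joins auxin to amino acids, by 1.72 ± 0.12. WRKY22 (AT4G01250) rose by 1.93 ± 0.12, P1R3 (AT3G29370) by 2.45 ± 0.14, EXLA1 by 1.47 ± 0.11 and the leucine degradation gene MCCA (AT1G03090) by 1.41 ± 0.10. Among the falls were the anthocyanin genes DFR (AT5G42800), which fell by 1.28 ± 0.19, and UF3GT (AT5G54060), which fell by 1.08 ± 0.12. GTR1, a glucosinolate transporter gene, fell by 1.00 ± 0.12 and SMZ, an AP2-like floral repressor gene, fell by 0.91 ± 0.10.

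By gene group, all 3 shade-response markers with a probe set named here, of 20 listed, rose at 1 h. FHL (AT5G02200), whose product helps phytochrome A into the nucleus, rose by 0.58 ± 0.12 as the smallest of them (3 adjusted over the list alone; camera adjusted p = 1.84e-09). Of 6 auxin genes 4 rose and 0 fell (4 adjusted over the list alone; camera adjusted p = 1.68e-08), among them the conjugation gene WES1 (AT4G27260) by 0.90 ± 0.08. IAA29 belongs to both lists. The call for 1 of the 4, the auxin synthesis gene YUC2 (0.43 ± 0.13), ended without WT WL0 replicate 2 (adjusted p = 0.0637) or WT FR1 replicate 3 (0.0909). All 3 flavonoid genes fell, UGT78D2 (AT5G17050) by 0.93 ± 0.08 and the acyltransferase gene AT5MAT by 0.64 ± 0.12 beside DFR (3 adjusted over the list alone; camera adjusted p = 7.36e-05). Of 8 wall-loosening genes, XTH33, EXPA4 and EXPA8 rose by 0.64, 0.57 and 0.56 and EXPB3 fell by 0.46 (4 adjusted over the list alone). Of 5 chlorophyll and carotenoid genes, GSA1, PORB and CHLI2 fell by 0.55, 0.40 and 0.39 (3 adjusted over the list alone). The camera adjusted p was 0.0257 for each of these 2 lists, with adjusted p = 0.162 with an estimated correlation for both. Leaving out WT WL0 replicate 3 (0.0577) or WT FR1 replicate 3 (0.0969) ended the wall-loosening call, and leaving out WT FR1 replicate 1 (0.0585) the chlorophyll call. The root hair expansin genes EXPA7 and EXPA18 fell by 0.60 ± 0.09 and 0.42 ± 0.10 (2 of 2, and 2 adjusted over the list alone).

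In all, 5267 of 22746 probe sets were called between FR1 and WL0 in the wild type by limma at an adjusted p under 0.05, 2432 higher and 2835 lower. Of these, 132 rose and 37 fell at least 2-fold. FR1 and FR3 seedlings were 1 h and 3 h older than the WL0 seedlings they were compared with, so elapsed time and far-red light cannot be told apart in either comparison.

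After 3 h, IAA29 stood at 9.59 ± 0.07, 31.0-fold above WL0. MGL (AT1G64660), the methionine gamma-lyase gene, rose by 2.75 ± 0.10, FHL by 2.37 ± 0.12 and IAA20 (AT2G46990), of the same family as IAA29, by 2.13 ± 0.15. The leucine degradation genes MCCA and IVD (AT3G45300) rose by 2.08 ± 0.10 and 1.83 ± 0.11, and P1R3, WRKY22, ATL8 and TCP15 (AT1G69690) by 1.96 to 2.60. The flavonoid genes DFR, UF3GT and CHIL (AT5G05270) fell by 3.53 ± 0.19, by 2.11 ± 0.12 and by 2.06 ± 0.09. RR16 (AT2G40670), a type-A response regulator gene, fell by 1.89 ± 0.17 and BGLU40 (AT1G26560), a beta-glucosidase gene, by 1.74 ± 0.10.

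All 3 shade-response markers had risen at 3 h (3 adjusted over the list alone; camera adjusted p = 1.87e-06), HAT2 by 1.13 ± 0.09. Of the 6 auxin genes 4 rose (4 adjusted over the list alone; camera adjusted p = 0.000111), WES1 by 1.32 ± 0.08, GH3.3 by 1.08 ± 0.12 and YUC2 by 0.74 ± 0.13. The 3 flavonoid genes fell (3 adjusted over the list alone; camera adjusted p = 5.42e-05), UGT78D2 by 1.48 ± 0.08. XTH19, XTH33, EXPA4 and EXPA8 rose by 0.88 to 1.45 while EXPB3 fell by 1.19 ± 0.12 and XTH16 by 0.27 ± 0.09 (6 of 8 adjusted over the list alone; camera adjusted p = 0.0509). Of 5 chlorophyll and carotenoid genes 4 fell (5 adjusted over the list alone), GSA1 by 1.05 ± 0.09 and CHLI2 by 0.66 ± 0.09; the camera adjusted p was 0.0034, and adjusted p = 0.0702 with an estimated correlation. PSBW, PSAN, LHCB4.2 and PSAE-1 rose by 0.29 to 0.45, 4 of 7 photosystem genes (4 adjusted over the list alone; camera adjusted p = 0.0281, and adjusted p = 0.164 with an estimated correlation). GI (AT1G22770), the only clock gene with a probe set named here, rose by 1.72 ± 0.13, and EIN3, the only such ethylene gene, by 0.62 ± 0.08. EXPA7 and EXPA18 fell by 1.02 ± 0.09 and by 0.97 ± 0.10. SPCH and STOMAGEN fell by 0.54 and by 0.46, 2 of 4 stomatal genes (2 adjusted over the list alone; camera adjusted p = 0.0984). Of 3 light-signalling genes FHL rose and HYH fell by 0.61 ± 0.09 (2 adjusted over the list alone; camera adjusted p = 0.605). The gibberellin receptor genes GID1A and GID1C were called higher, by 0.30 ± 0.08 and 0.34 ± 0.12, 2 of 3 genes of that list (2 adjusted over the list alone; camera adjusted p = 0.305), but GID1C was not called without WT WL0 replicate 1 (adjusted p = 0.241), WT FR3 replicate 2 (0.0818) or WT FR3 replicate 3 (0.0872). Of 4 reference genes for expression assays, PEX4 rose by 0.51 ± 0.09 and SAND by 0.28 ± 0.08; the third, TIP41L (0.23 ± 0.07), was not called without WT FR3 replicate 1 (adjusted p = 0.07). The reference list had a camera adjusted p of 0.0509 (3 adjusted over the list alone).

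Between FR3 and WL0, 8217 probe sets were called in the wild type, 4115 higher and 4102 lower, with 449 up and 438 down at least 2-fold. Of the 2432 probe sets risen at 1 h, 1993 had also risen at 3 h, against 440.0 for independent lists, and of the 2835 fallen 2225 had also fallen, against 511.3. Unchanged groups simulated against the shared WL0 arrays gave 0 in each direction. Such groups give few calls that could overlap, so this cannot measure what shared arrays add among many real changes. As both comparisons share those 3 control arrays, part of the excess may come from them.

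From 1 h to 3 h, MGL and FHL rose further in the wild type, by 1.84 ± 0.10 and 1.78 ± 0.12. GI rose by 1.82 ± 0.13 over the same time, having stood at 4.79 ± 0.15 at WL0 and 4.69 ± 0.19 at 1 h. HAT2 and GH3.3 fell by 0.77 ± 0.09 and by 0.63 ± 0.12 from their 1 h levels, and IAA29 differed by 0.27 ± 0.13 (adjusted p = 0.137). DFR fell by 2.25 ± 0.19 from 1 h to 3 h, RR16 by 1.82 ± 0.17 and GH3.9 by 1.30 ± 0.14. The flavonoid list was lower at 3 h than at 1 h (camera adjusted p = 0.000692), with 2 of 3 genes fallen and 3 adjusted over the list alone. In all 4586 probe sets were called, 2328 higher and 2258 lower, 241 of them at least 2-fold.

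After 24 h of far-red light, against 24 h of white light, THI2.2 (AT5G36910), a thionin gene, rose 8.17-fold to 12.37 ± 0.12 in the wild type, and GI rose 8.05-fold to 7.81 ± 0.32. LHCB4.3 (AT2G40100), of the light-harvesting antenna, rose by 1.91 ± 0.12, the sucrose phosphate synthase gene ATSPS4F (AT4G10120) by 1.58 ± 0.14, the cold-regulated gene COR27 by 1.34 ± 0.14 and XTH26 by 1.34 ± 0.17. IAA29 was still higher, by 1.46 ± 0.13, while HAT2 fell by 0.68 ± 0.09 and P1R3 by 1.60 ± 0.14. VTC4 (AT3G02870), of ascorbate synthesis, fell by 1.82 ± 0.09, RR16 by 1.77 ± 0.17, BGLU40 by 1.73 ± 0.10 and the glycosyl hydrolase gene GH9B8 (AT2G32990) by 1.64 ± 0.12.

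Of the 3 shade-response markers 1 rose and 1 fell (2 adjusted over the list alone; camera adjusted p = 0.897), and FHL differed by -0.09 ± 0.12 (adjusted p = 0.683). GH3.3 fell by 0.60 ± 0.12, and the auxin list had 1 rise and 2 falls among 6 genes (3 adjusted over the list alone; camera adjusted p = 0.707). The WES1 fall (-0.26 ± 0.08) was not called without WT FR24 replicate 1 (adjusted p = 0.0854) or WT WL24 replicate 2 (0.0716). EXPB3, EXPA8 (AT2G40610) and EXPB1 fell by 1.19 ± 0.12, by 1.07 ± 0.11 and by 0.93 ± 0.11, 3 of 8 wall-loosening genes (3 adjusted over the list alone; camera adjusted p = 0.0916). PORB (AT4G27440), a protochlorophyllide reductase gene, fell by 1.52 ± 0.10 and CHLI2 by 0.35 ± 0.09. With CHLM (-0.22 ± 0.07) they made 3 falls and 0 rises among 5 chlorophyll and carotenoid genes (4 adjusted over the list alone; camera adjusted p = 0.0916), but the CHLM call ended without WT FR24 replicate 1 (adjusted p = 0.0922), WT FR24 replicate 2 (0.0535) or WT WL24 replicate 3 (0.0863). Of 7 photosystem and Rubisco genes, LHCB4.2 and PSAE-1 fell by 0.53 ± 0.07 and by 0.37 ± 0.07, and RCA was called higher by 0.19 ± 0.06 (3 adjusted over the list alone; camera adjusted p = 0.164). The RCA call ended without any 1 of 4 of the 6 arrays, with a highest adjusted p of 0.139. The root hair expansins EXPA7 and EXPA18, lower at 1 h and 3 h, rose by 0.85 ± 0.09 and 0.67 ± 0.10. With the 24 h younger WL0 seedlings as the control, EXPA7, EXPA18 and XTH26 fell by 1.29, by 1.18 and by 0.99, and LHCB4.2 and PSAE-1 were not called (adjusted p = 0.114 and 0.379). The cold genes COR47 and COR15A differed by 0.26 ± 0.12 and 0.01 ± 0.10 and the jasmonate gene PDF1.2 by 0.09 ± 0.09, with 0 of these 3 called.

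In the wild type, this is the only far-red comparison with a control of the same age. It called 5283 probe sets, 2641 higher and 2642 lower, with 180 up and 156 down at least 2-fold. Of the 4115 probe sets risen at 3 h, 588 had also risen at 24 h and 860 had fallen. Independent lists would share 477.8 risen. Of the 4102 fallen at 3 h, 648 had also fallen, against 476.5 for independent lists, and 1031 had risen. From 1 h to 24 h, 298 of the risen were shared, against 282.4, with 605 opposite, and 361 of the fallen, against 329.3, with 812 opposite. These comparisons share no array.

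**Figure D2:**
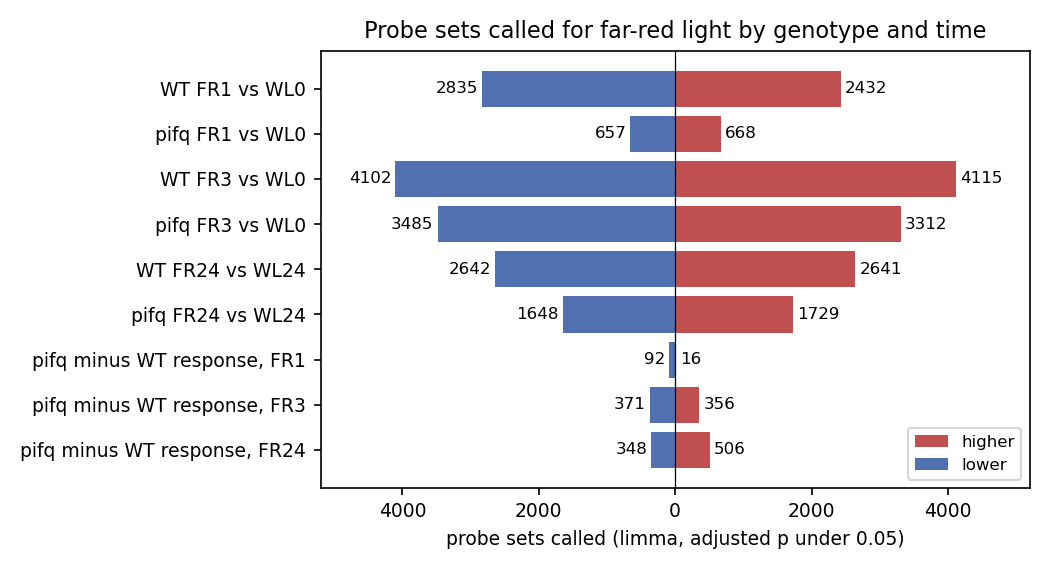
Bars give the number of probe sets called by limma at an adjusted p under 0.05 (x axis), higher to the right and lower to the left of 0, for each far-red comparison (y axis). The differences between the responses of pifq and the wild type, in the lowest 3 bars, called 108, 727 and 854 probe sets, against 5267, 8217 and 5283 in the wild type.

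The 24 h response in the wild type was set against the 3 h response by the difference of the 2 log2 changes. The difference was -4.20 ± 0.20 for P1R3, -3.50 ± 0.18 for IAA29, -2.45 ± 0.17 for FHL and -1.81 ± 0.13 for HAT2. In the other direction the difference was 3.93 ± 0.27 for DFR, 3.32 ± 0.20 for ATSPS4F, 3.08 ± 0.16 for LHCB4.3 and 2.62 ± 0.14 for THI2.2. The difference was negative for all 3 shade-response markers (3 adjusted over the list alone; camera adjusted p = 6.67e-06) and for 4 of 6 auxin genes (4 adjusted over the list alone; camera adjusted p = 0.00154), with HAT2, GH3.3 and WES1 called higher at 3 h and lower at 24 h. It was positive for all 3 flavonoid genes (3 adjusted over the list alone; camera adjusted p = 0.000174). The call for 1 of the 4 auxin genes, YUC2 (-0.50 ± 0.18), ended without any 1 of 5 of the 12 arrays, with a highest adjusted p of 0.0881. In all 7909 probe sets were called, 3876 positive and 4033 negative. The difference also holds the age difference between FR3 and WL0 seedlings.

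**Figure D3:**
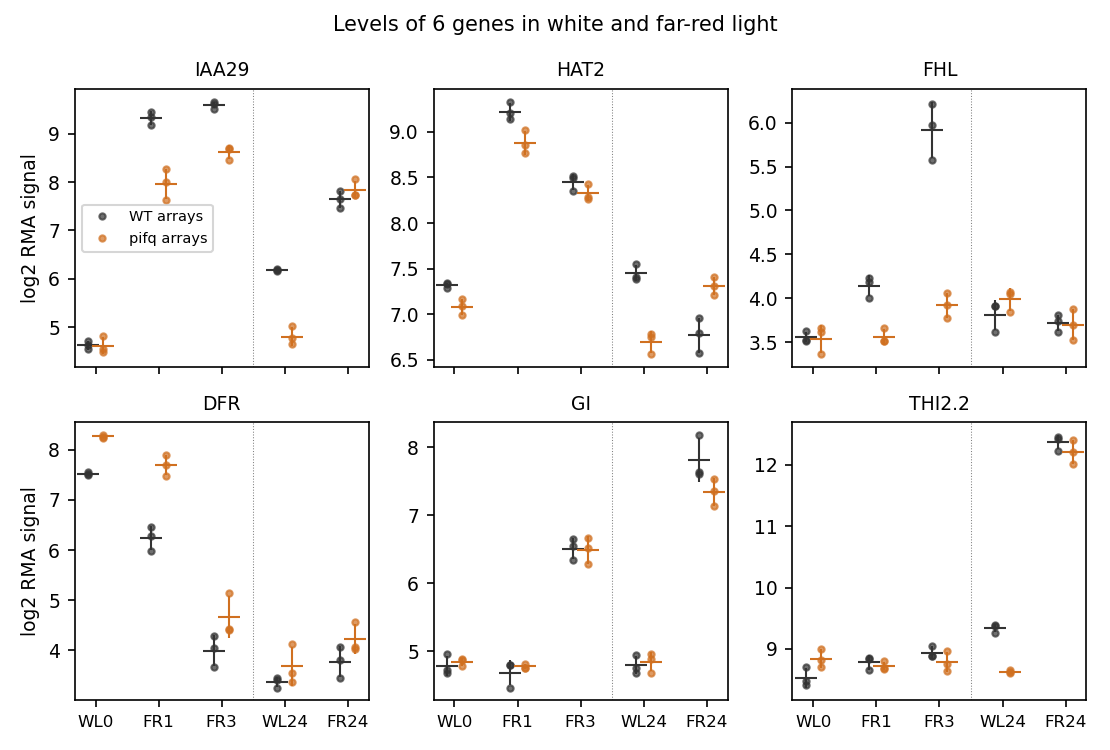
Log2 RMA signal (y axis) of 6 genes in the 5 light conditions (x axis), with 1 point per array in grey for the wild type and orange for pifq, and a bar and whiskers for the mean ± SD of 3 arrays. IAA29 reached 9.59 in the wild type and 8.62 in pifq at FR3, and FHL reached 5.92 and 3.92.

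In pifq under far-red light, IAA29 rose by 3.34 ± 0.13 at 1 h, by 3.99 ± 0.13 at 3 h and by 3.03 ± 0.13 at 24 h. HAT2 rose by 1.80 ± 0.09 and GH3.3 by 1.74 ± 0.12 at 1 h, and MCCA by 2.14 ± 0.10 and GI by 1.64 ± 0.13 at 3 h. UF3GT and CHIL fell by 2.35 ± 0.12 and by 2.05 ± 0.09 at 3 h, and ATSPS4F fell by 1.94 ± 0.14. At 24 h THI2.2 rose by 3.58 ± 0.10 and GI by 2.50 ± 0.13, HAT2 rose by 0.61 ± 0.09, and RR16, BGLU40 and VTC4 fell by 1.50 ± 0.17, by 1.34 ± 0.10 and by 1.13 ± 0.09.

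The shade-response markers rose as a list at 1 h, 3 h and 24 h in pifq (camera adjusted p = 2.13e-11, 1.29e-05 and 0.00136), with 2, 3 and 2 of 3 genes risen, and 2, 3 and 3 changed when adjusted over the list alone. With WL0 as the control, the 24 h list call ended (adjusted p = 0.0624). FHL differed by 0.02 ± 0.12 at 1 h and by -0.29 ± 0.12 at 24 h. Its rise by 0.37 ± 0.12 at 3 h was not called without pifq WL0 replicate 3 (0.28, adjusted p = 0.127) or pifq FR3 replicate 3 (0.30, adjusted p = 0.0992). Auxin genes rose at 1 h and 3 h, 3 and 4 of 6 (4 and 5 adjusted over the list alone; camera adjusted p = 2.86e-12 and 1.53e-06). Flavonoid genes fell, 2 and 3 of 3 (3 and 3 adjusted over the list alone; camera adjusted p = 1.51e-06 and 2.07e-07). The 1 h call for AT5MAT (-0.53 ± 0.12) ended without pifq WL0 replicate 3 (adjusted p = 0.0716) or pifq FR1 replicate 2 (0.0517). At 3 h XTH33 rose by 1.11 ± 0.12, EXPB3 fell by 1.14 ± 0.12, and 6 of 7 photosystem genes rose (6 adjusted over the list alone; camera adjusted p = 0.000932, and adjusted p = 0.0672 with an estimated correlation). Of these 6, the call for LHCB4.1 (0.22) ended without pifq WL0 replicate 1 (adjusted p = 0.178), pifq FR3 replicate 1 (0.0537) or pifq FR3 replicate 3 (0.0974), and that for PSBY (0.27) without pifq WL0 replicate 3 (0.0525).

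The number of probe sets called in pifq was 1325 at 1 h (668 higher, 657 lower), 6797 at 3 h (3312 and 3485) and 3377 at 24 h (1729 and 1648). Of those called in the wild type, 569 of 2432 risen and 512 of 2835 fallen at 1 h were called the same way in pifq, against 71.4 and 81.9 for independent lists. At 3 h it was 2678 of 4115 and 2885 of 4102 (599.2 and 628.5), and at 24 h 1084 of 2641 and 859 of 2642 (200.8 and 191.4). The 1 h count was 845 without pifq FR1 replicate 2, 805 without the pifq replicate 1 arrays of WL0, FR1 and FR3, and 2405 with array weights. The 24 h count was 2212 without pifq WL24 replicate 2 and 1685 when only the arrays compared were fitted.

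Whether the 2 lines responded differently was tested by the difference between the response in pifq and in the wild type. With 1 line per genotype, an effect of the mutations on the response cannot be told apart from one of background or seed stock. At 1 h and 3 h the difference also holds any difference between the lines in change with elapsed time. At 1 h the response of IAA29 was smaller in pifq by 1.35 ± 0.18 (difference -1.35, adjusted p = 3.04e-05), and differences were -1.13 ± 0.20 for P1R3 and -1.07 ± 0.19 for LEA4-5 (AT5G06760), a late embryogenesis abundant gene. LEA4-5 went from 7.02 ± 0.25 to 7.99 ± 0.15 in the wild type and from 9.41 ± 0.14 to 9.31 ± 0.05 in pifq. At 3 h the differences were -1.99 ± 0.17 for FHL (adjusted p = 2.01e-09), -1.72 ± 0.13 for MGL, -1.67 ± 0.21 for IAA20 and -0.96 ± 0.18 for IAA29, while GH3.9, TBL45 and BGLU40 gave 1.42 ± 0.19, 1.03 ± 0.13 and 0.92 ± 0.14. At 24 h IAA29 and P1R3 gave 1.57 ± 0.18 and 1.56 ± 0.20, opposite in sign to their 1 h differences. HAT2 gave 1.29 ± 0.13, EXPA8 1.69 ± 0.15 and PORB 1.28 ± 0.14, and LHCB4.3 and ATSPS4F gave -1.03 ± 0.16 and -0.89 ± 0.20.

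The response of HAT2 was not called as different at 1 h or 3 h (-0.11 ± 0.13 and 0.12 ± 0.13, adjusted p = 0.802 and 0.854), nor was that of GI at 3 h (-0.07 ± 0.18, adjusted p = 0.953). The difference of the shade-response list was negative at 1 h and 3 h (camera adjusted p = 0.000133 and 4.73e-05) and positive at 24 h (6.31e-05), with 1, 2 and 2 of 3 genes called and 2 each time when adjusted over the list alone. The wall-loosening list was higher at 24 h (camera adjusted p = 0.000131), with 3 of 8 genes called (3 adjusted over the list alone), EXPA8, EXPB3 by 0.78 ± 0.16 and EXPB1 by 0.53 ± 0.15. The EXPB1 call ended without any 1 of 8 of the 12 arrays, with a highest adjusted p of 0.126.

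The interaction called 108 probe sets at 1 h (16 positive, 92 negative), 727 at 3 h (356 and 371) and 854 at 24 h (506 and 348). The 1 h count is unsteady: it was 338 without WT FR1 replicate 3, when 34.9% were positive, 68 without pifq WL0 replicate 2, 180 with trend and robust settings, and 714 with array weights, when 47.9% were positive against 14.8%. The 3 h count was 1247 with array weights, and the 24 h count 389 when only the arrays compared were fitted. Over the probe sets changed at least 2-fold in the wild type, the mean response in pifq was 64.5% of the wild-type response at 1 h, 68.2% at 3 h and 59.9% at 24 h. To avoid selecting on the values compared, probe sets were chosen from the other wild-type replicates and the wild-type response was measured in the 1 held out. The 3 ways of holding out gave SDs of 3.3, 2.8 and 0.4 percentage points. These ways share arrays and held out only wild-type replicates, so the SDs are not errors of the shares. The probe sets were chosen by the wild-type response alone, which can lower the share in pifq.

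In white light at WL0, among genes with a symbol, M17 (AT2G41260) was higher in pifq than in the wild type by 3.05 ± 0.33, and LEA18 (AT2G35300), LEA (AT2G21490) and LEA4-5 by 2.47 ± 0.14, 2.45 ± 0.18 and 2.39 ± 0.13. No list of late embryo genes could be tested. QQS (AT3G30720), an orphan gene linked to starch, was 11.61 ± 0.02 in pifq and 6.77 ± 0.28 in the wild type, a difference of 4.84 ± 0.10. Among genes with a symbol, ATL8, MCCA and NRPB9A were lower, by -0.68 ± 0.15, -0.62 ± 0.10 and -0.56 ± 0.09. The ATL8 call ended without any 1 of 2 of the 6 arrays (highest adjusted p 0.112). Larger falls lay in probe sets without a locus here: 6 probe sets were at least 2-fold lower, the largest differences being -3.77 ± 0.08 and -3.34 ± 0.11. Flavonoid genes were higher in pifq as a list at WL0 (camera adjusted p = 1.99e-07), with 3 of 3 called (3 adjusted over the list alone). UGT78D2 differed by 0.49 ± 0.08. AT5MAT (0.61 ± 0.12) was not called without pifq WL0 replicate 3 (adjusted p = 0.0579), nor DFR (0.75 ± 0.19) without any 1 of the 6 arrays (0.0836 to 0.127). IAA29, HAT2 and FHL differed by -0.01 ± 0.13, -0.24 ± 0.09 and -0.01 ± 0.12, with 0 of 3 called (1 adjusted over the list alone). The comparison called 380 probe sets, 282 higher and 98 lower in pifq. With 1 line per genotype, the mutations and the background or seed stock of the line cannot be told apart. The count was 244, 239 and 237 without WT WL0 replicate 1, WT WL0 replicate 2 and pifq WL0 replicate 3, and 1116 with array weights.

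In WL24, QQS was higher in pifq by 4.42 ± 0.10, PAP85 (AT3G22640) by 1.78 ± 0.23, LEA by 1.74 ± 0.18 and ATOEP16-2 (AT4G16160) by 1.63 ± 0.18. Among genes with a symbol, GH9B8 and IAA29 were lower, by -1.51 ± 0.12 and -1.37 ± 0.13, HAT2 by -0.75 ± 0.09 and EXPA8 by -0.82 ± 0.11. The largest falls, -4.44 ± 0.08 and -3.00 ± 0.11, lay in probe sets without a locus here. The shade-response and auxin lists were lower in pifq (camera adjusted p = 0.000897 and 0.0013), with 2 of 3 and 3 of 6 genes called (2 and 3 adjusted over the list alone). The test called 1957 probe sets, 978 higher and 979 lower, and 572 when only the arrays compared were fitted.

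Under far-red light, QQS stayed higher in pifq by 4.61, 4.72 and 4.46 (± 0.10 each) at 1 h, 3 h and 24 h, and LEA by 1.85, 1.50 and 2.42 (± 0.18 each). At FR1, P1R3, IAA29, P1R1 and TCP15 were lower in pifq by -1.53 ± 0.14, -1.36 ± 0.13, -1.07 ± 0.11 and -1.07 ± 0.15, and DFR was higher by 1.44 ± 0.19. At FR3, FHL, IAA20, MGL and WRKY22 were lower by -2.00 ± 0.12, -2.00 ± 0.15, -1.88 ± 0.10 and -1.40 ± 0.12. At FR24, PORB was higher by 1.54 ± 0.10, EXPA8 by 0.87 ± 0.11 and HAT2 by 0.53 ± 0.09, and TRY and ATSPS4F were lower by -0.90 ± 0.14 and -0.88 ± 0.14. IAA29 then differed by 0.20 ± 0.13 (adjusted p = 0.371). These are genes with a symbol. The largest falls lay in a probe set without a locus here, which was lower in pifq by -4.16 ± 0.08 at FR1, -4.78 ± 0.08 at FR3 and -4.94 ± 0.08 at FR24.

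The shade-response list was lower in pifq at FR1 and FR3 (camera adjusted p = 2.36e-05 and 5.65e-06), with 3 and 2 of 3 genes called (3 and 2 adjusted over the list alone). The call for HAT2 at FR1 (-0.35 ± 0.09) ended without pifq FR1 replicate 1 (-0.29, adjusted p = 0.0731). Flavonoid genes were higher at FR1 (camera adjusted p = 2.36e-05), 3 of 3 (3 adjusted over the list alone). The counts called were 3102 at FR1 (1610 higher, 1492 lower), 2262 at FR3 (1245 and 1017) and 1891 at FR24 (1016 and 875). The FR1 count was 1713 without WT FR1 replicate 1, 1906 without pifq FR1 replicate 1 and 1947 without the pifq replicate 1 arrays of WL0, FR1 and FR3. The FR3 count was 1492 without pifq FR3 replicate 3, and the FR24 count 1225 when only the arrays compared were fitted.

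**Figure D4:**
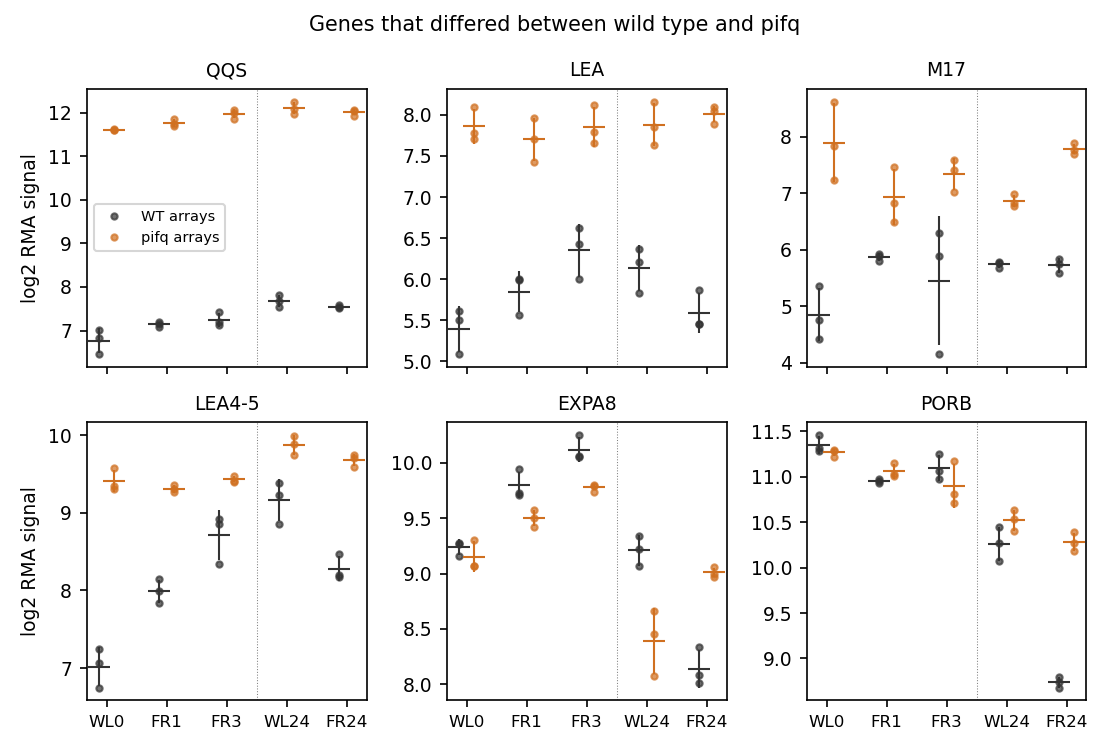
Log2 RMA signal (y axis) of 6 genes in the 5 light conditions (x axis), with 1 point per array in grey for the wild type and orange for pifq, and a bar and whiskers for the mean ± SD of 3 arrays. QQS lay at 6.77 to 7.68 in the wild type and 11.61 to 12.10 in pifq, and PORB fell to 8.74 in the wild type at FR24 against 10.28 in pifq.

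The far-red response of the wild type was compared with the genotype difference across probe sets called in either. So that the 2 comparisons shared no array, the genotype difference was that at WL24 for the 1 h and 3 h responses and that at WL0 for the 24 h response, and the 24 h value therefore does not differ from the others by time alone. The Pearson correlation was -0.34 at 1 h (6315 probe sets), -0.33 at 3 h (8903) and 0.07 at 24 h (5486), with Spearman values of -0.40, -0.38 and 0.17. Unchanged groups simulated with the same arrays gave -0.01, 0.00 and 0.00. Covariances were -0.0526, -0.063 and 0.0116. Probe sets are not independent replicates, so no p is given. The 1 h and 3 h responses also hold elapsed time, and pifq arrays lay below wild-type arrays on principal component 1 at WL24. A lag of pifq seedlings could therefore also give a negative correlation at 1 h and 3 h, which was not tested.

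Between WL0 and WL24, HIS1-3 (AT2G18050), a linker histone gene, rose by 4.76 ± 0.14 in the wild type, COR27 by 3.25 ± 0.14, OSM34 by 3.03 ± 0.17 and LEA18 by 2.87 ± 0.14. DFR fell by 4.15 ± 0.19, Cpn60beta2, a chaperonin gene, by 2.87 ± 0.10, and GH3.3 by 2.31 ± 0.12. EXPA7 and EXPA18 fell by 2.14 ± 0.09 and by 1.85 ± 0.10, GSA1 and CHLI2 by 1.96 ± 0.09 and by 1.44 ± 0.09, and IAA29 rose by 1.55 ± 0.13. Of 5 chlorophyll and carotenoid genes 3 fell and 2 rose (5 adjusted over the list alone; camera adjusted p = 0.105), of which LYC (0.25) was not called without WT WL24 replicate 3 (adjusted p = 0.0595). Of 8 wall-loosening genes 6 fell and 0 rose (6 adjusted over the list alone; camera adjusted p = 0.00416, and adjusted p = 0.107 with an estimated correlation), and the 3 flavonoid genes fell (3 adjusted over the list alone; camera adjusted p = 0.00416, and adjusted p = 0.0931 with an estimated correlation). The reference gene PEX4 rose by 0.88 ± 0.09. In pifq HIS1-3 rose by 3.95 ± 0.14 and OSM34 by 3.07 ± 0.17, and DFR fell by 4.59 ± 0.19. There 7 of 8 wall-loosening genes and 3 of 3 flavonoid genes fell (7 and 3 adjusted over the lists alone; camera adjusted p = 0.00019 for each). The wild type had 10950 probe sets called (5579 higher, 5371 lower) and pifq 11216 (5806 and 5410), of which 1777 and 1445 changed at least 2-fold. These counts exceed those of each far-red comparison above.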

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

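The tests on genes higher in pifq under all conditions as an earlier stage, on the 24 h white-light level and on splits with the genotype difference subtracted were chosen only after the results were seen, and the added families were chosen after the table was seen.

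The values here are differences between 2 responses that passed a test of the difference itself, between genotypes or, in the wild type, between 24 h and 3 h. At 1 h, 108 probe sets differed in response between pifq and the wild type, among them M17 (-1.99), IAA29 (-1.35), P1R3 (-1.13) and LEA4-5 (-1.07). The M17 call ended without any 1 of 8 of the 12 arrays, with a highest adjusted p of 0.168. At 3 h, 727 differed, among them GH3.9 (1.42), TBL45 (1.03), BGLU40 (0.92), CLE41 (0.90), VTC4 (0.85), ATERDJ2B (0.78), FHL (-1.99), MGL (-1.72), IAA20 (-1.67), LEA4-5 (-1.67) and IAA29 (-0.96). At 24 h, 854 differed, among them EXPA8 (1.69), IAA29 (1.57), P1R3 (1.56), GH9B8 (1.33), HAT2 (1.29), PORB (1.28), LHCB4.3 (-1.03), TRY (-0.99), ATSPS4F (-0.89) and CYP71B26 (-0.83). The 24 h response of the wild type differed from its 3 h response for 7909 probe sets, among them DFR (3.93), ATSPS4F (3.32), LHCB4.3 (3.08), CHIL (2.65), THI2.2 (2.62), UF3GT (2.34), P1R3 (-4.20), IAA29 (-3.50), LEA4-5 (-2.57) and MGL (-2.55).

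Mean differences of fixed lists called by camera were -0.67 at 1 h, -0.95 at 3 h and 0.89 at 24 h between genotypes and -2.59 between times for shade-response markers. For auxin genes they were 0.39 (24 h between genotypes; adjusted p = 0.0529 with an estimated correlation) and -1.18 (between times), for wall-loosening genes 0.46 (24 h) and -0.76 (between times; adjusted p = 0.0626 with an estimated correlation), and for flavonoid genes 2.17 (between times). Chlorophyll genes gave 0.22 at 3 h (adjusted p = 0.128 with an estimated correlation) and light-signalling genes -0.72 at 3 h, where 1 of 3 genes, FHL, was called (1 adjusted over the list alone). Gibberellin genes gave -0.27 at 3 h (adjusted p = 0.113 with an estimated correlation), a call that ended without any 1 of 4 of the 12 arrays (WT WL0 replicate 1, WT FR3 replicate 3, pifq WL0 replicate 3 or pifq FR3 replicate 1; highest adjusted p 0.134). Photosystem genes gave 0.15 at 24 h (adjusted p = 0.329 with an estimated correlation), a call that ended without any 1 of 7 of the 12 arrays (highest adjusted p 0.119), and -0.40 between times (adjusted p = 0.148 with an estimated correlation).

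Among the added families, autophagy genes gave -0.29 at 1 h and -0.22 at 3 h between genotypes and -0.82 between times (adjusted p = 0.399, 0.462 and 0.275 with an estimated correlation). The 3 h autophagy call ended without pifq WL0 replicate 2 (0.0579) or pifq FR3 replicate 3 (0.113). OTP and CRR genes gave 0.21 at 3 h (0.0928 with an estimated correlation, as an adjusted p) and 0.68 between times (adjusted p = 0.0217). IQ-domain genes gave -0.27 at 3 h, not called without WT FR3 replicate 1 (0.0587), and -0.44 between times, not called without any 1 of 4 of the 12 arrays (highest adjusted p 0.123), with estimated-correlation adjusted p of 0.118 and 0.275. RNA polymerase subunit genes gave -0.21 at 1 h and -0.21 at 3 h (adjusted p = 0.399 and 0.43 with an estimated correlation). Their 1 h call ended without WT WL0 replicate 2 (0.052) or WT FR1 replicate 1 (0.135), and the 3 h call without any 1 of 4 of the 12 arrays (highest adjusted p 0.065). The IAA, GH3 and YUC families gave 0.23 at 24 h (adjusted p = 0.0967 with an estimated correlation), not called without any 1 of 6 of the 12 arrays (highest adjusted p 0.0798), and -0.64 between times (0.0671 as an adjusted p with an estimated correlation). SWEET sugar transporter genes gave 0.23 at 3 h (adjusted p = 0.0928 with an estimated correlation) and UDP-glycosyltransferases 0.23 between times (0.275).

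Other splits of the same arrays were counted for each comparison. The 14 comparisons of 3 arrays with 3 have only 10 splits, too few for a share under 0.05, and the real split was 1 of 10 in each. The highest count in any other split was 0 for WT FR1 (real 5267), 0 for WT FR3 (8217), 1 for WT FR24 (5283), 0 for pifq FR1 (1325), 0 for pifq FR3 (6797), 4 for pifq FR24 (3377), 1 and 0 for WL24 against WL0 in the wild type (10950) and pifq (11216), and 0 for WT FR3 against FR1 (4586). For pifq against the wild type it was 0 at WL0 (380), 22 at WL24 (1957), 0 at FR1 (3102), 1 at FR3 (2262) and 1 at FR24 (1891). For the interactions, 13 of 100 splits within conditions gave as many calls at 1 h (highest other 1765), 7 of 100 at 3 h (1078) and 2 of 100 at 24 h (1175). The bound set beforehand was a share under 0.05, which only the 24 h count met. Many of the other splits mix the genotypes within a group, which can lower their counts. Chance is therefore not excluded by this count at any of these times. Splits that exchange different numbers of arrays in the 2 conditions carry part of the genotype difference itself. Of those that differed by 0 arrays, 0 of 34 (1 h), 0 of 39 (3 h) and 0 of 37 (24 h) gave as many. Such splits place both genotypes in each group, so the genotype difference cancels from the contrast and widens the spread. They give few calls whatever the cause, so this count decides nothing about chance. With the mean genotype difference subtracted, 1 of 100 gave as many at each time (highest other 14, 137 and 70). For the 24 h against the 3 h response, plain splits gave as many in 1 of 100 (highest other 5597), a share under the same bound. Splits with the mean far-red difference subtracted were not counted for this comparison, so chance is not excluded by this count.

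Much of the 3 h response of the wild type went the same way as the change over 24 h of white light in pifq, on arrays not used for the 3 h response. Of 887 probe sets changed at least 2-fold, 650 (73.3%) were called the same way, among them DFR, MGL, FHL and RR16, and 84 (9.5%) the opposite way, among them IAA20, HAT2, GH3.3 and XTH19. The share called opposite fell between the bounds set for and against elapsed time as the whole cause, so that stays undecided. The ratio of 7.74 is what elapsed time as part of the 3 h response would give, but a far-red effect on the same genes is as open, since the design has no 3 h white-light control. A change over 24 h also need not show what 3 h of time brings. In pifq, GI stood at 4.85 at both WL0 and WL24 but at 6.49 at FR3. These counts therefore do not decide for or against elapsed time. After 24 h of far-red, against white light of the same age, 208 of the 650 were called opposite to their 3 h change and 163 the same way, against 25 and 28 of the 84.

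A set of 21 probe sets was at least 2-fold higher in pifq under all 5 conditions, which held 15 single loci, among them QQS, M17, M10 (AT2G41280), LEA, PAP85 and ATOEP16-2. Another 5 were at least 2-fold lower under all 5 conditions, none of them with a locus here. For these 15 loci, an earlier stage between WL0 and WL24 is argued against, because 0% fell and 12 rose in the wild type over that time. Stages before WL0 were not measured, and the same white-light arrays helped to choose the loci. A lag of pifq seedlings as a whole stays open. On principal component 1, pifq arrays lay below wild-type arrays in all 5 conditions. At WL24 they lay at 26.34 to 34.18, against 39.54 to 41.22 in the wild type. The deviations of the 15 loci from group means correlated across pifq arrays at a mean of 0.49, the 100th percentile of 1000 random sets (median 0.03, 95th percentile 0.12). Varying carry-over of seed RNA may give this, but the value in the wild type was 0.65, so co-regulation is as open. The random sets were matched on mean level only, so any set of co-regulated genes could rank as high. The test therefore cannot tell carry-over from co-regulation. A difference in line background or seed stock cannot be told apart from the mutations, since QQS was higher in 5 of 5 conditions and no other line was measured. An effect of the missing factors stays open too.

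For 129 probe sets the interaction was called both at 24 h and at 1 h or 3 h (28.2 by chance), and in 56 its sign was opposite, negative first and positive at 24 h in 46, as for IAA29, P1R3 and LEA4-5 (0.69 at 24 h). Between-array scaling stays open: 0 signs turned under quantile normalization or centring, but the values were already quantile normalized and these settings moved the 24 h interaction by a median of at most 0.0308 (median SE 0.139). A single deviating array stays open as part of the cause: 0 signs turned with any 1 of the 12 arrays of the 24 h interaction left out, but a difference carried by 1 array alone reaches an absolute t of at most 1.92 and the lowest here was 3.44, so the test could not turn a sign, and the 1 h and 3 h arrays were not left out. For 21 of the 56 (37.5%), IAA29 (-1.37 and 0.20) but not P1R3 or LEA4-5 among them, the genotype difference was larger at WL24 than at FR24, between the bounds set for and against a difference in the 24 h white-light level as the cause, which stays undecided. A change in what these factors do over 24 h may also account for it and was not tested.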

How the results depend on the processing

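The alternative without the pifq replicate 1 arrays and all tests of the added families were chosen after the data were seen. Some 24 h results turned direction with WL0 as the control, as given below, and none of those recomputed under the other alternatives did. With these exceptions the counts of calls stayed within 1.5 times of those reported: array weights gave 2405 for pifq FR1, 714 for the interaction at 1 h (47.9% higher, against 14.8%), 1247 for that at 3 h and 1116 for pifq against WT at WL0, and trend and robust settings gave 180 for the interaction at 1 h. Fitting only the arrays compared gave 1685 for pifq FR24, 389 for the interaction at 24 h, and 572 and 1225 for pifq against WT at WL24 and FR24, with fewer arrays to estimate the spread. With only probe sets of 1 locus, fewer probe sets were tested. The counts for FR1, FR3 and FR24 were then 2606, 4321 and 2654 in the wild type, 595, 3470 and 1627 in pifq, and 47, 318 and 369 for the interaction. For pifq against WT they were 182, 933, 1492, 1076 and 898 (WL0, WL24, FR1, FR3, FR24), for WL24 against WL0 5860 and 6054 (wild type, pifq), for FR3 against FR1 2354 and for the 24 h against the 3 h response 4077. With WL0 as the control in place of WL24, which adds 24 h of age, FR24 gave 10874 in the wild type and 10606 in pifq. Of 40 genes of the naming rule in the wild type 7 then changed sign, 5 of them called with either control: EXPA7 (-1.29), EXPA18 (-1.18), XTH26 (-0.99), UGT78D2 (-0.32), STOMAGEN (0.40), CHLM (0.10) and TIP41L (0.091). Of 34 in pifq 9 did, 4 of them called with either control: DFR (-4.04), EXPA7 (-1.42), EXPA18 (-1.22), UGT78D2 (-0.99), XTH16 (-0.56), EXPA8 (-0.14), LHCB4.3 (-0.10), PSAN (0.39) and CHLM (0.18). Lists called only with WL0 and in the other direction were flavonoid genes (mean -1.75 in the wild type, -2.20 in pifq), wall-loosening genes in pifq (-0.80), and the XTH and expansin families (-0.43) and autophagy genes (0.52) in the wild type. Lists called only with WL0 and in the same direction were wall-loosening (-1.09, camera adjusted p = 0.000167) and chlorophyll genes (-1.17, 0.0341) in the wild type and autophagy genes in pifq (0.66, 0.0023), the last with a mean of 0.00 with WL24. List calls that ended were those of IQ-domain genes and histones in the wild type (adjusted p = 0.137 each), and of shade-response markers (0.0624), auxin genes (0.91), glutathione S-transferases (0.98) and histones (0.331) in pifq. Among other members of the added families, 23 of 82 and 16 of 58 changed sign. Without the pifq replicate 1 arrays of WL0, FR1 and FR3, which deviated together (correlations of 0.28, 0.17 and 0.12), pifq FR1 gave 805 and pifq against WT at FR1 1947, with fewer arrays, and named genes lost 98 calls and gained 2. An estimated correlation lowered the list calls from 52 to 31 and those of the added families from 45 to 7, as it widens the error of a list. Apart from the counts explained by fewer probe sets, fewer arrays or added age, the cause was not tested.

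With 1 array left out in turn, the interaction at 1 h called 68 to 338 (68 without pifq WL0 replicate 2, 338 without WT FR1 replicate 3), pifq against WT 237 to 303 at WL0 (244, 239 and 237 without WT WL0 replicate 1, WT WL0 replicate 2 and pifq WL0 replicate 3), 1713 to 3281 at FR1 (1713 without WT FR1 replicate 1, 1906 without pifq FR1 replicate 1) and 1492 to 2334 at FR3 (1492 without pifq FR3 replicate 3). The pifq response called 845 to 1042 at 1 h (845 without pifq FR1 replicate 2) and 2212 to 3213 at 24 h (2212 without pifq WL24 replicate 2). Of 488 called named genes and comparisons, 91 lost the call with 1 array left out and 0 turned direction. Named genes, uncalled ones included, lost and gained calls in 194 and 17 cases with only the arrays compared, 48 and 53 with array weights, 42 and 11 after quantile normalization, 27 and 9 after centring and 31 and 15 with trend and robust settings. The 180 tests of fixed lists lost and gained 8 and 0 calls without the dimmest 30% of probe sets, 2 and 1 after quantile normalization, 1 and 2 after centring, 1 and 3 with array weights and 0 and 11 with trend and robust settings. How far a probe set stood above background was not analysed here, so no limit from a low signal is given.

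Without a fold threshold, the share of the wild-type response seen in pifq was 56.0%, 72.5% and 57.3% at 1 h, 3 h and 24 h. It was 60.4%, 64.5% and 67.6% over risen and 80.9%, 72.7% and 50.7% over fallen probe sets. The correlation of response with genotype difference was -0.11, -0.11 and 0.23 with shared control arrays, that is with the genotype difference at WL0, WL0 and WL24 (0.50 in simulated unchanged groups), and -0.28 and -0.29 at 1 h and 3 h over all probe sets. Restricted to calls of at least 2-fold, the overlaps for risen and fallen probe sets were 110 and 37 for WT FR1 with FR3, 34 and 31 for FR3 with FR24, 11 and 1 for FR1 with FR24, and, between genotypes, 51 and 12 at 1 h, 208 and 147 at 3 h and 60 and 31 at 24 h.

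With the replicate number as a block, WT FR1 and FR3 called 5321 and 8261, the interaction at 1 h 120 and pifq against WT at WL0 371, and 56 list tests were called; no count of calls of a comparison moved by over 1.5 times. By the rule that every pair correlates over 0.1, arrays that share a number were not taken as paired: their deviations correlated at a mean of 0.01 (-0.21 to 0.28), 19 of 135 pairs were over 0.1, those of pifq replicate 1 among them, and 15 of 30 arrays correlated best with their own number.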

Other observations

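The added families were chosen after the table was seen and before their results were computed, and no hypothesis beyond those above was tested here.

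Autophagy genes, whose products deliver cell contents to the vacuole for breakdown, were higher under far-red light in the wild type, 8 of 10 at 1 h (mean 0.48) and 9 of 10 at 3 h (mean 0.70), with 0 lower at either time (camera adjusted p = 1.11e-06 and 7.31e-06). The calls did not hold with an estimated correlation (adjusted p = 0.291 and 0.342). In white light over 24 h, 7 of the 10 rose in the wild type and 9 in pifq (camera adjusted p = 0.00905 and 0.0019; adjusted p = 0.835 and 0.634 with an estimated correlation), so their rise at 1 h and 3 h also carries the limit of elapsed time. OTP and CRR genes, many of them for factors of organelle RNA processing, fell at 3 h in the wild type, 8 of 13 with a mean change of -0.52 and 0 higher (camera adjusted p = 0.00163; adjusted p = 0.0375 with an estimated correlation). They were also lower at 3 h than at 1 h, 6 of 13 (camera adjusted p = 0.004).

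After 24 h of far-red light all 6 histone genes with a probe set named here fell in the wild type, with a mean change of -0.54 (camera adjusted p = 0.000243), and 3 of 6 in pifq, with a mean of -0.38 (0.00352), where 0 rose. The estimated-correlation adjusted p was 0.252 and 0.348, and with WL0 as the control neither was called (mean -0.03 and 0.10; camera adjusted p = 0.137 and 0.331). Within pifq, glutathione S-transferase genes were lower at FR24 than at WL24, 4 of 13 with a mean of -0.26 (camera adjusted p = 0.00527; adjusted p = 0.348 with an estimated correlation, and 0.98 with WL0 as the control), GSTU20 among them, which fell by 1.08 ± 0.09. The auxin families IAA, GH3 and YUC, 16 probe sets of which IAA29 is 1, were higher at 1 h, 7 of 16 in the wild type and 4 in pifq (camera adjusted p = 3.36e-05 and 1.31e-06).

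Of 45 calls in the added families, 21 ended with 1 array left out, 2 of which stand here as values. UDP-glycosyltransferases had a mean of -0.14 in WT FR1 (camera adjusted p = 0.0383, 0.0906 without WT FR1 replicate 2 and 0.0564 without WT WL0 replicate 3; adjusted p = 0.291 with an estimated correlation). The XTH and expansin families had a mean of -0.44 in WT WL24 against WL0 (camera adjusted p = 0.0316, and 0.0547 without WT WL0 replicate 2; adjusted p = 0.361 with an estimated correlation). AGAMOUS-like, serine carboxypeptidase-like, trichome birefringence-like, beta-glucosidase, tetraspanin, bZIP, ubiquitin, subtilase, vesicle transport, RALF-like, response regulator, tubulin and WRKY families were called by camera in 0 of the 18 comparisons.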
